A study of Mus musculus with 4 samples.

How the data were processed

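The series holds 4 RNA sequencing libraries of macrophages sorted from mouse sciatic nerve 3 days after injury, 2 from young and 2 from aged females, each made from pooled mice. Per the labels' protocols, sorted cells went straight into lysis buffer, the RNA of all samples was extracted together, and complementary DNA was primed with oligo-dT and amplified by multiple displacement before Illumina library preparation. Such amplification is used for very small RNA amounts and can copy transcripts unevenly, which the number of reads does not show. Groups and replicate numbers were taken from the sample titles, and the columns were matched to samples by the sample numbers in the labels, with 0 columns left unmatched. Which mice went into which pool is not given in the sources used here, so the p-values of single genes measure the spread between these pooled samples, which may be technical.

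The deposited table gives 24028 mouse genes, with Entrez IDs and symbols, in FPKM (fragments per kilobase of gene scaled to the library's read total) calculated by the authors. Per the submitters' processing notes, bcl2fastq, BWA 0.7.12, DESeq2 and the genome build mm10 were used, with no role given for each. The counting program, the annotation and any filter are not given in the sources used here, and mitochondrially encoded genes were not analysed here.

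The scaling of the deposited values varied from gene to gene. With the genes ordered by Entrez ID sorted as text, the values had been divided in turn by 12 read totals that repeat every 12 genes and continue from the end of a column into the next, with a shift of 4 places per column. The 12 totals were found from the values, reduced within each gene to a ratio of whole reads, and from exon lengths of GENCODE M21 matched by symbol. Each total was the most common result over genes, shared by 122 to 143 genes. Each came out as a whole number of reads within 0.0011 reads. The restored scale thus rests in part on that annotation. The first 4, 11489336, 10765234, 8613360 and 9986706 reads, stand at the places of the 4 columns, and the reads recovered from the columns add up to 97.9%, 97.9%, 97.9% and 97.7% of them. The other 8 totals belong to none of the 4 libraries. Only 8.3% of the values of a column had been divided by that library's own total. In the values as deposited this shifts the log2 difference of aged minus young by -0.64 to 0.13 depending on the gene's place, with a median of -0.24 and an SD of 0.18. Each value was therefore multiplied by the total it had been divided by and divided by its own library's total. The design had been to use the values as the authors scaled them. The change was made after the values were seen and before any test was fitted, and the values as deposited were kept as an alternative. With the totals undone, the values of 22888 of the 22888 genes above 0 were whole multiples of 1 read within 0.05 reads (100%), and the other 1140 genes were at 0 in every library. Genes not solved from the ratios of their values were accepted at any length that gave whole reads. The 100% is therefore no test of the totals. The recovered reads are the smallest whole numbers possible, so a gene whose reads and length share a factor is undercounted, which leaves the restored FPKM as they are.

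The test was limma on log2(FPKM + 1) of the restored values, with empirical Bayes and an intensity trend, aged against young, two-sided, over the 11656 genes with a mean FPKM of at least 1. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. The camera p-value rests mainly on the spread between genes, taken as nearly independent. It measures the spread between the pools only in part. The test, the lists, the rule for named genes and the alternatives listed first below were fixed before the data were examined. The 36 lists were written from textbook knowledge, with 887 entries. Of these entries, 851 matched a symbol of the table, 5 matched through RefSeq IDs, and 31 had no match. The 32 lists with at least 5 tested members were tested. Mast cells and related granulocytes (4 members tested), red cells (2), the sex check (2) and the mitochondrially encoded genes had too few.

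By the rule, the genes named were in each direction the 12 with the smallest p whose aged values lie all above or all below the young values and whose higher group has a mean of at least 5 FPKM, filled with genes that do not pass where too few pass. Gene models without a common name were skipped. Of each list, up to 4 members past the threshold over all genes or over the list alone were named, or otherwise the 2 with the highest mean FPKM. Cx3cr1, Ccr2, Adgre1, Csf1r, Lyz2, Il1b, Tnf, Il6, Il10, Ccl2, Arg1, Mrc1, Nos2, Tgfb1, Cdkn1a, Cdkn2a, Mertk, Apoe and Spp1 were always given, with the sex-linked genes as a check of the labels. Cox7b in its list, the further interferon genes beyond Isg15, Ifit3, Ifit2 and Rtp4, and the genes of symbol families and of single libraries were chosen after their values were seen.

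Alternatives fixed at the start were pseudocounts of 0.1 and 5, no filter or a mean FPKM of at least 5, rescaling to the same sum, by the median ratio or by quantiles, empirical Bayes without the trend or robust, the replicate number as a block, each library left out in turn, only genes above 0 in all 4 libraries, and, for lists, an estimated correlation, fry, and members of 1 list only. Added after seeing the data were the values as deposited, log2 CPM (reads scaled to the library total) and voom on the recovered reads, and, for lists, fold changes with a smooth trend on gene length and GC content removed. Gene families were formed from symbols up to the first digit or hyphen, with at least 10 tested genes, leaving out the stems Fam, Tmem, LOC, Gm and those of a single letter, which join unrelated genes. Lengths came from the deposited values once the totals were known, and GC content from the longest GENCODE M21 transcript of each symbol. Both were found for 11250 of the 11656 genes. Coordinates are those of RefSeq on GRCm38.p6, matched by Entrez ID, and exon overlaps are those of GENCODE M21 on either strand. Shared sequence was counted as 50-base stretches of a gene's GENCODE M21 transcripts that also occur, on either strand, in those of a gene elsewhere.

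The steps were tested on simulated data. Reads were drawn for all 24028 genes from the real means and totals, with a spread between libraries estimated from the real values, and divided by the 12 totals in turn. All 12 totals were found exactly, and the reads of 96.0% of the 22369 genes above 0 came out as drawn. For aged against young over 11649 simulated genes, 200 genes had been changed by log2 sizes of 1 to 4. At an adjusted p of 0.05, limma called 1 of 46 tested genes of size 1, 19 of 49 of size 2, 28 of 45 of size 3 and 39 of 47 of size 4, and 3 unchanged genes. The interferon list, shifted by -0.7, was found lower (adjusted p 2.62e-17), and 0 of the 30 lists that share no member with it were called. Simulated genes vary independently, so this does not test the effect of correlation between genes on the list test.

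R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.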

Results

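Macrophages were sorted from the injured sciatic nerve of female mice 3 days after injury, from young animals of 3 months and aged animals of 15 months. The mice were heterozygous for the reporters Cx3cr1-GFP and Ccr2-RFP, which mark monocytes and macrophages, and the labels call the cells positive for Ccr2 and Cx3cr1. The submitters give 7 to 8 mice per time point, pooled into 2 libraries per age. The comparison asks how macrophages of the injured nerve differ in their transcripts between young and aged animals. The read totals recovered from the table were 11489336 and 10765234 for the young libraries and 8613360 and 9986706 for the aged libraries. Between 19897 and 21361 of the 24028 genes had a value above 0 in a library, and 1 read in a gene of 2 kb was worth 0.0435 to 0.0580 FPKM. Values are FPKM on each library's own read total, as mean ± SD (n = 2 libraries) unless single libraries are given. Differences are aged minus young on the scale of log2(FPKM + 1), which understates the change of low genes.

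All 4 libraries had high levels of macrophage transcripts. The most abundant transcript was that of Lyz2, lysozyme, in both young libraries (12267 and 9886 FPKM) and that of Grn, progranulin, in both aged libraries (11913 and 11652 FPKM). Csf1r, the receptor for the growth factor CSF1, was 217 ± 55.1 FPKM in young and 270.0 ± 11.5 FPKM in aged cells, and Adgre1, which encodes F4/80, was 130.2 ± 10.4 and 105 ± 3.52 FPKM. Of the reporter loci, Ccr2 was 316 ± 56.5 FPKM in young and 372 ± 38.7 FPKM in aged cells, and Cx3cr1 was 18.5 ± 0.612 and 17.9 ± 2.61 FPKM. As a check of the labels, Xist, the X-inactivation transcript of female cells, lay between 17.5 and 30.6 FPKM. The Y-linked genes Kdm5d, Uty and Ddx3y were at most 0.0689 FPKM, and Eif2s3y was listed at 0 in all 4 libraries.

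The clearest difference between the ages was in the interferon response genes, which were lower in aged macrophages. All 36 members were tested, 34 of them had a lower mean log2 value in aged cells, and in 29 both aged libraries lay below both young libraries. The median log2 difference was -0.66 (quartiles -0.86 and -0.44), a level 1.58-fold higher in young. Isg15, a ubiquitin-like protein induced by type I interferon (chromosome 4, 156199424 to 156200818, GRCm38), was 94.4 ± 16.6 FPKM in young and 35.8 ± 8.17 FPKM in aged macrophages, a log2 difference of -1.38 (SE 0.25). The antiviral genes Ifit3 (54.1 ± 3.67 against 25.8 ± 0.370 FPKM; chromosome 19, 34583119 to 34588982) and Ifit2 (78.0 ± 5.25 against 39.6 ± 3.97 FPKM) had log2 differences of -1.04 (SE 0.20) and -0.96 (SE 0.21). Rtp4, also induced by interferon, was 44.9 ± 1.93 FPKM in young and 21.5 ± 5.64 FPKM in aged cells. Both values of Ifit3 and Oas1a are uncertain in part, since 51.2% of the 50-base stretches of Ifit3 also occur in Ifit3b and 57.6% of those of Oas1a in Oas1g. Ifit3b itself was 15.8 and 20.2 FPKM in the young and 7.82 and 5.77 FPKM in the aged libraries. The aged libraries lay apart in Gbp5, at 35.7 FPKM in aged replicate 1 and 2.73 FPKM in aged replicate 2.

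limma's camera test, which compares a list with all other genes, gave the interferon list an adjusted p of 5.58e-13 among 32 lists. With an estimated correlation the adjusted camera p was 0.806, and none of the 32 lists had a lower one in that setting. It was 0.150 with fry, which asks whether the genes move on balance in the same direction. Over 22 alternatives the adjusted p ranged from 1.56e-16 to 0.806. None of the 36 genes passed over all genes tested, and 9 were lower adjusted over the list alone: Isg15, Ifit3, Ifit2, Rtp4, Herc6, Mx2, Ifi204, Slfn5 and Ifi44. Relative to all genes tested, the list's mean was 0.29 and 0.28 in the young libraries and -0.31 and -0.21 in the aged libraries on the log2 scale. The difference of -0.54 between the ages was thus larger than the gaps of 0.01 within the young pair and 0.10 within the aged pair.

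**Figure D1:**
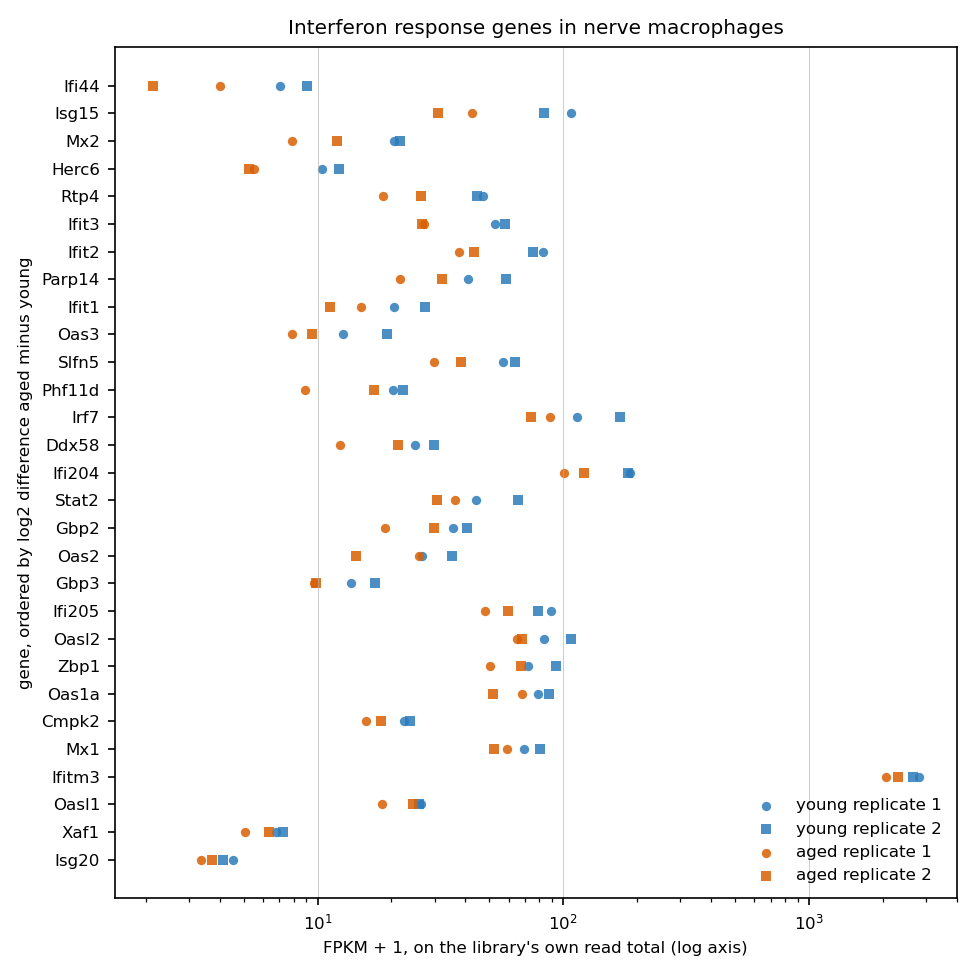
FPKM + 1 of the 29 interferon response genes in which both aged libraries lay below both young libraries, on a log axis, with young libraries in blue and aged libraries in orange, circles for replicate 1 and squares for replicate 2. The genes were picked by this separation, and the other members of the list are not drawn.

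Genes of oxidative phosphorylation, nuclear genes for the respiratory chain and ATP synthase, were also lower in aged macrophages, by less. Of 70 members tested, 57 had a lower and 13 a higher mean log2 value in aged cells, with a median of -0.32 (quartiles -0.65 and -0.14). In 31 members both aged libraries lay below both young libraries and in 5 they lay above. The values of some members are uncertain in part, since they share sequence with genes elsewhere. Of the 50-base stretches of Atp5g2, 36.7% also occur in Gm10175, and 25.25% of those of Cycs occur in Gm10053. Cox7b, a subunit of cytochrome c oxidase, was 16.9 ± 2.08 FPKM in young and 5.53 ± 1.03 FPKM in aged cells. The most abundant members did not share that direction, with Cox4i1 at 734 ± 84.9 and 1132 ± 341 FPKM and Uqcrh at 378.4 ± 27.3 and 378.3 ± 12.7 FPKM. The camera test of limma gave an adjusted p of 3.33e-04, with an adjusted p of 0.806 with an estimated correlation and 0.322 with fry, and no member passed over all genes or adjusted over the list alone. Without young replicate 1 the median was -0.23 (quartiles -0.56 and -0.07) beside -0.18 for all genes, and the adjusted p was 0.181, in a range of 2.40e-06 to 0.806 over 22 alternatives, and the difference of -0.28 between the ages was smaller than the gap of 0.31 between the young libraries.

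**Figure D2:**
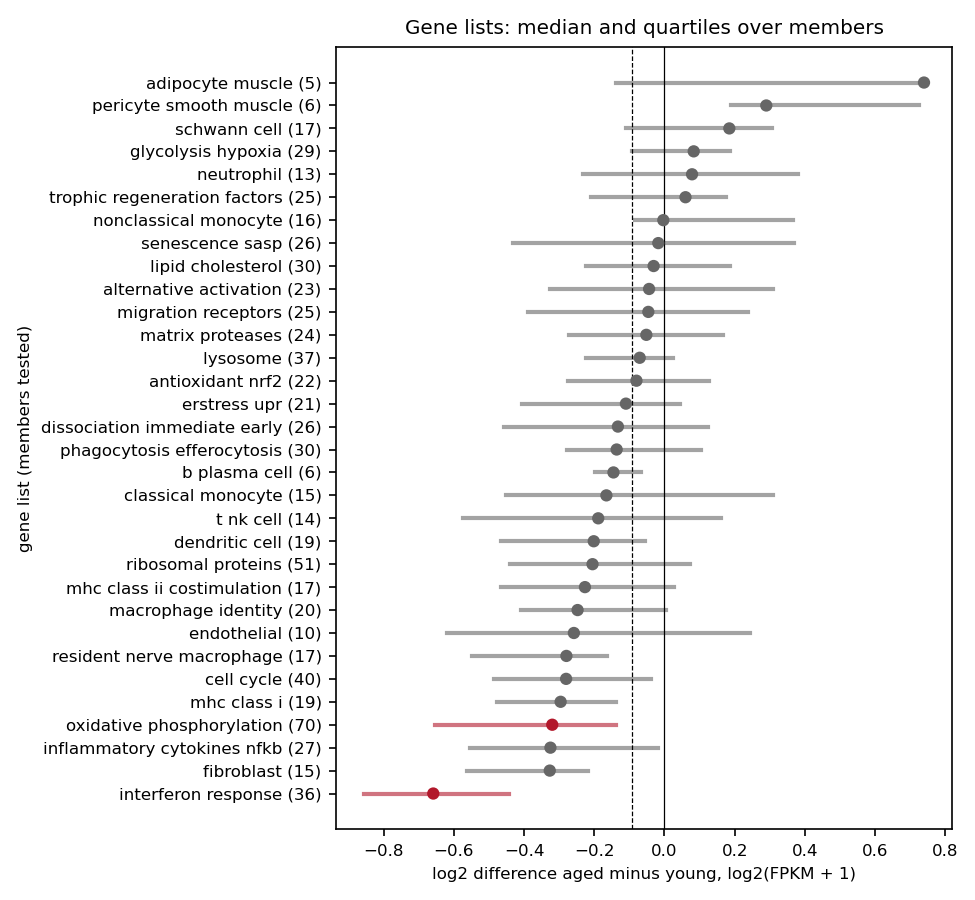
Median (point) and quartiles (line) of the log2 difference, aged minus young, over the members of each of 32 gene lists, with the number of members in brackets. The dashed line is the median of all genes tested (-0.09), and red marks the 2 lists past the camera threshold, interferon response (-0.66) and oxidative phosphorylation (-0.32).

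The other 30 lists did not pass the camera test of limma, and the values of their genes follow. Inflammatory cytokine genes had a median of -0.32 over 27 members (adjusted p 0.151), with a wider gap within the young pair than between the ages. Ccl7, a chemokine that attracts monocytes, was 3488 and 949 FPKM in the young and 2042 and 1464 FPKM in the aged libraries, and Il1b was 1107 ± 408 and 841 ± 101 FPKM. Tnf was 88.4 ± 22.6 FPKM in young and 69.0 ± 13.6 FPKM in aged cells, Il6 was 19.4 ± 3.06 and 11.2 ± 4.43 FPKM, and Il10 was 112 ± 72.2 and 105 ± 8.66 FPKM. Nos2, at 0.627 to 1.83 FPKM, was below the minimum for testing. The median of the inflammatory list was 0.04 without young replicate 1 (adjusted p 0.0128) and -0.62 without young replicate 2 (adjusted p 1.78e-09), in a range of adjusted p up to 0.917 over the alternatives.

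Genes of alternative activation went both ways (median -0.04 over 23 members, adjusted p 0.722). Retnla, an effector of the response to interleukin 4 (chromosome 16, 48842609 to 48844461), was lower in aged cells adjusted over the list alone (limma, adjusted p 0.0292), at 209 ± 24.9 FPKM in young and 95.4 ± 5.13 FPKM in aged cells. Arg1 was 598 ± 293 and 685 ± 126 FPKM, Mrc1 343 ± 32.1 and 282 ± 0.370 FPKM, and Tgfb1 64.0 ± 6.89 and 83.6 ± 4.19 FPKM. The median of this list was 0.09 without young replicate 1 (adjusted p 0.0424) and -0.34 without young replicate 2 (adjusted p 0.00551), with adjusted p up to 0.982 over the alternatives. In the classical monocyte list (median -0.17, adjusted p 0.805), Ms4a4c was lower adjusted over the list alone (adjusted p 0.0117), at 91.8 ± 6.06 and 39.2 ± 0.104 FPKM. The non-classical monocyte list had an adjusted p of 0.407, with Nr4a1 at 322 ± 48.7 and 304 ± 5.56 FPKM and Tnfrsf1b at 127 ± 3.97 and 118 ± 10.5 FPKM.

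Macrophage identity genes had a median of -0.25 (adjusted p 0.134), with Cd14 at 985 ± 339 FPKM in young and 1095 ± 215 FPKM in aged cells. Resident nerve macrophage markers had a median of -0.28 (adjusted p 0.271), with Sepp1 at 2217 ± 406 and 1726 ± 485 FPKM and F13a1 at 379 ± 38.2 and 601 ± 92.2 FPKM. MHC class I genes had a median of -0.30 (adjusted p 0.0736), with B2m at 1333 ± 291 and 793 ± 20.03 FPKM and H2-D1 at 1154 ± 57.8 and 816 ± 158 FPKM. MHC class II and costimulation genes had a median of -0.23 (adjusted p 0.572), which ranged from -0.332 to -0.111 without a single library. Of these genes, Ctss was 2567 ± 378 and 2003 ± 374 FPKM, and Cd74 was 1573 and 1759 FPKM in young and 1961 and 1467 FPKM in aged libraries. With quantile scaling, the macrophage identity and MHC class I lists were called lower (limma's camera, adjusted p 0.0116 and 0.0129, with highest values of 0.806 and 0.844 over their alternatives). The MHC class I list was also called lower without a filter on low values (0.0301), without young replicate 1 (0.00708) and with the trend on gene length and GC content removed (0.0385), and the macrophage identity and resident lists without young replicate 2 (0.0211 and 0.0189, with 0.871 as the highest of the resident list).

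Of the lists for clearing and rebuilding the nerve, those for phagocytosis, the lysosome, lipid handling, matrix proteases and migration lay close to the median of all genes (-0.09). Trophic factors and glycolysis genes lay above it, with a wider gap within the young pair than between the ages. Phagocytosis genes had a median of -0.14 (adjusted p 0.805), with the complement genes C1qc at 993 and 1015 FPKM in young and 1061 and 860.2 FPKM in aged libraries and C1qb at 412 ± 14.1 and 457 ± 214 FPKM. Mertk, a receptor for apoptotic cells, was 51.3 ± 10.2 and 45.4 ± 5.13 FPKM. The medians were -0.07 for the lysosome (0.805), -0.03 for lipid handling (0.407), -0.05 for matrix proteases (0.805) and -0.05 for migration receptors (0.805), adjusted p in brackets. Apoe was 2151 ± 114 FPKM in young and 2186 ± 932 FPKM in aged cells, Tgfbi 506 ± 28.2 and 473 ± 9.42 FPKM, Thbs1 972 ± 404 and 889 ± 17.5 FPKM, and Cd44 298 ± 74.1 and 318 ± 8.92 FPKM. Trophic factors (median 0.06, adjusted p 0.407) and glycolysis genes (0.08, adjusted p 0.151) held Fn1 at 1227 ± 204 and 1342 ± 179 FPKM, Spp1 at 1122 ± 595 and 716 ± 87.1 FPKM, Ldha at 170 ± 14.5 and 182 ± 0.264 FPKM and Tpi1 at 171 ± 45.3 and 213 ± 36.8 FPKM. Both lists were called higher without young replicate 1 (limma's camera, adjusted p 3.61e-04 and 3.63e-04, with highest values of 0.988 and 0.947 over their alternatives).

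Cell cycle genes had a median of -0.28 over 40 members, 31 of them with a lower mean log2 value in aged cells (adjusted p 0.151), with Pcna at 61.2 ± 4.24 and 47.5 ± 2.94 FPKM. Senescence and secretory genes had a median of -0.02 (adjusted p 0.805). Cdkn1a, the cell cycle inhibitor p21, was 87.1 ± 0.538 FPKM in young and 73.6 ± 9.33 FPKM in aged cells, Cdkn2a was at most 0.204 FPKM, Ccl2 was 1207 ± 807 and 713 ± 74.2 FPKM, and Ccl8 was 345 ± 62.8 and 144 ± 48.8 FPKM. Ribosomal protein genes had a median of -0.20 (adjusted p 0.191), with Rpl4 at 1463 ± 210 and 2025 ± 4.69 FPKM and Rplp0 at 651 ± 113 and 791 ± 269 FPKM. The antioxidant list (median -0.08, adjusted p 0.875) held the ferritin genes Fth1 (1969 ± 746 and 1834 ± 192 FPKM) and Ftl1 (1191 ± 387 and 1734 ± 224 FPKM), which shares 47.3% of its 50-base stretches with Ftl1-ps1. The endoplasmic reticulum stress list (-0.11, adjusted p 0.422) held Hspa5 (332 ± 30.7 and 225 ± 50.3 FPKM) and Hsp90b1 (219 ± 0.164 and 227 ± 20.8 FPKM). Immediate early genes, induced by tissue dissociation, had a median of -0.13 (adjusted p 0.407), with Fos at 1025 ± 312 and 964 ± 255 FPKM and Dusp1 at 855 ± 31.7 and 1001 ± 144 FPKM. The senescence list was called higher without young replicate 1 (limma's camera, adjusted p 0.0234), and the ribosomal list lower without young replicate 2 (1.11e-04) and without aged replicate 1 (3.63e-04), with highest values of 0.951 and 0.917 over their alternatives.

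Markers of other cells of the nerve were also read, and none of their lists passed. Schwann cell markers had a median of 0.18 over 17 members (adjusted p 0.151), with Egr2, which macrophages can also express, at 93.8 ± 0.760 and 112 ± 12.2 FPKM and Pmp22 at 40.9 ± 15.1 and 31.2 ± 4.64 FPKM. Fibroblast markers had a median of -0.33 over 15 members (adjusted p 0.686). Dcn, decorin, was 9.73 and 42.8 FPKM in the young and 29.9 and 20.7 FPKM in the aged libraries, and Gsn was 86.6 ± 8.59 and 85.8 ± 3.67 FPKM. Endothelial (-0.26, adjusted p 0.805) and pericyte markers (0.29, adjusted p 0.132) were low, with Ly6c1 at 19.5 ± 7.12 and 11.1 ± 0.778 FPKM, Eng at 7.82 ± 1.66 and 6.60 ± 1.38 FPKM, Acta2 at 6.29 ± 1.57 and 7.85 ± 1.34 FPKM and Notch3 at 9.97 FPKM in aged replicate 1 against at most 2.06 FPKM elsewhere. The values of Ly6c1 are uncertain, since 21.5% of its 50-base stretches also occur in Ly6c2. Ly6c2, of the classical monocyte list, was 164 ± 54.9 and 88.1 ± 4.36 FPKM. All 6 pericyte markers tested had a higher mean log2 value in aged cells. The difference of 0.62 in the list's mean was larger than the gaps of 0.14 and 0.09 within an age. The list's median ranged from 0.0493 to 0.570 without a single library. In only 1 of the 6, Myh11 (0.410 and 0.705 against 5.64 and 1.38 FPKM), did both aged libraries lie above both young libraries. The list holds 12 markers, and those not tested had a mean below 1 FPKM. Of these, Pdgfrb, Cspg4, Kcnj8, Des and Cnn1 had a lower mean FPKM in aged cells and Abcc9 a higher one. Neutrophil (0.08, adjusted p 0.422) and dendritic cell markers (-0.20, 0.407) held Il1r2 at 56.5 ± 29.6 and 55.7 ± 18.9 FPKM, Mmp9 at 22.7 ± 9.60 and 32.2 ± 5.16 FPKM, Bst2 at 60.3 ± 16.1 and 43.5 ± 25.1 FPKM and Irf8 at 42.5 ± 12.5 and 48.5 ± 0.165 FPKM. T and NK cell markers had a median of -0.19 (adjusted p 0.805), with Klrd1 at 11.8 ± 0.9005 and 6.85 ± 1.34 FPKM and Cd3g at 97.8 FPKM in aged replicate 2 and at most 1.54 FPKM in the other libraries. In the B cell list (-0.15, adjusted p 0.602) Pax5 was higher in aged cells adjusted over the list alone (0.793 and 0.461 against 18.7 and 4.48 FPKM, adjusted p 0.0287). The list of adipocytes and muscle had a median of 0.74 over 5 members (adjusted p 0.407), and of 0.129 to 0.725 without a single library. Its member Tnnc2 was lower adjusted over the list alone (3.52 and 4.16 against 0.839 and 0 FPKM, adjusted p 0.0351). The exons of Tnnc2 overlap those of Ube2c, and it had 28 and 31 against 5 and 0 reads, so its values are uncertain. Without young replicate 1, limma's camera called the fibroblast list lower (median -1.38, adjusted p 4.80e-08) and the neutrophil list higher (0.0234), and without young replicate 2 the fibroblast list higher (median 0.58, adjusted p 0.00120) and the Schwann cell list higher (0.0189), with highest values over their alternatives of 0.990, 0.988 and 0.864 for fibroblasts, neutrophils and Schwann cells.

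Gene by gene, limma's test called 0 genes higher and 0 lower among 11656 genes, with 0.567 as the lowest adjusted p. At an unadjusted p below 0.05 there were 773 genes, 205 higher and 568 lower in aged cells, where 583 would be found without any difference. The excess was small with the median ratio, at 596 genes for 581 expected, and absent without a filter on low values, at 1021 for 1144 expected. It was larger with a mean FPKM of at least 5, at 565 for 354 expected, and with quantile scaling, at 794 for 583 expected. The number of such genes depended on single libraries, with 381 genes without young replicate 1, 480 without young replicate 2 and 1437 without aged replicate 1, and without aged replicate 2 the 816 genes were 425 higher and 391 lower. limma on log2 CPM of the recovered reads also called 0 genes, with 744 at an unadjusted p below 0.05 (249 higher and 495 lower), as did voom, with 679 (215 higher and 464 lower). Both aged libraries lay above both young libraries in 1377 genes and below them in 3057 genes, together 38.0% of genes, where chance gives 33.3% for 2 against 2. The share of lower genes among the 773 was 73.5%, against 51.0% after rescaling by the median ratio, 58.4% after quantile scaling, 66.6% after rescaling to the same sum and 93.5% in the values as deposited. The median log2 difference of all genes was -0.09, against 0.01 with the median ratio and -0.31 as deposited. In 8 lists the median, the mean and the direction of the camera test differed in sign.

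**Figure D3:**
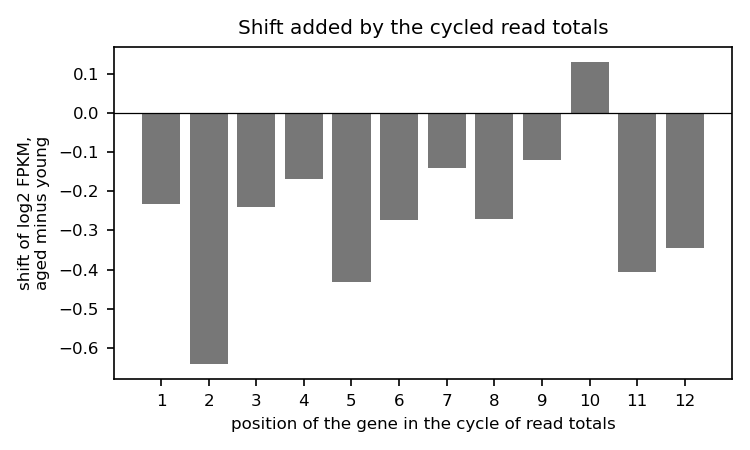
Shift of the log2 difference, aged minus young, that the read totals used in the deposited table add to a gene, for each of the 12 places in their cycle (bars). The shift runs from -0.64 to 0.13, and it was removed before testing.

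The genes nearest to the threshold are given here, none of them past it (limma, adjusted p 0.567 for Tcp11, 0.638 for Lars2 and 0.740 for the others). Values were higher in aged cells for Lars2, the mitochondrial leucyl-tRNA synthetase (chromosome 9, 123366927 to 123462675), at 59.4 ± 26.7 against 429 ± 52.1 FPKM, a log2 difference of 2.90 (SE 0.33). They were also higher for Tcp11 (0.699 ± 0.280 against 13.9 ± 0.673 FPKM), the myeloid transcription factor gene Cebpe (1.09 ± 0.153 against 9.14 ± 2.05 FPKM) and Rab43 (126 ± 29.5 against 336 ± 62.0 FPKM). Apoc2, an activator of lipoprotein lipase, was 615 ± 187 and 1499 ± 262 FPKM, Mcm7, a subunit of the replicative helicase, was 22.9 ± 1.93 and 50.1 ± 7.15 FPKM, and Dnase2a, a lysosomal DNase, was 10.2 ± 0.738 and 49.6 ± 25.7 FPKM. Zswim7, Tmem120a, Arpc1a, Hsf4 and Grtp1 had log2 differences from 0.96 (Arpc1a) to 2.62 (Hsf4).

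Values were lower in aged cells for the ubiquitin ligase gene Nedd4 (18.6 and 25.4 against 4.91 and 5.998 FPKM), the cohesin gene Smc1a (32.6 ± 1.61 against 11.9 ± 0.209 FPKM) and the nuclear non-coding RNA Malat1 (153 ± 44.4 against 53.6 ± 3.24 FPKM). Ikbke, a kinase that acts upstream of interferon genes, was 44.3 ± 6.60 and 18.9 ± 0.480 FPKM, and Ndufa13, a subunit of respiratory complex I, was 20.3 ± 2.93 and 5.86 ± 0.916 FPKM. Isg15, Ms4a4c, Retnla and Cox7b, with values above, belonged to the same 12, and Bola2, Mzt2 and Myeov2 had log2 differences of -1.84, -2.41 and -1.55. Exons of Tcp11, Rab43, Dnase2a, Arpc1a, Mcm7, Apoc2, Grtp1, Bola2, Ndufa13, Ms4a4c, Malat1 and Ikbke overlap those of another gene, and 16.5% of the 50-base stretches of Mcm7 occur in Gm5487. Further genes named earlier have such overlaps, among them Rtp4, Grn, Csf1r, Cox4i1, F13a1 and Tpi1. The strand used in counting is not given in the sources used here, so the values of all genes with such overlaps are uncertain.

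By both correlations, the young libraries were closer to each other than any pair across ages, and the aged libraries were further apart than any such pair. Across the genes tested, which are not independent replicates, Pearson's r of the log2 values was 0.960 between the young and 0.909 between the aged libraries, against 0.919 to 0.941 for the 4 pairs across ages. Spearman's rho was 0.949, 0.882 and 0.898 to 0.926 for the same pairs. By the median absolute log2 difference, the young pair (0.308) was again the closest, while the aged pair (0.352) lay within the range across ages (0.332 to 0.402). The mean r within an age exceeded that between ages by 0.00436, less than the SD of 0.0117 among the pairs across ages. The first principal component, with 47.3% of the variance, set aged replicate 2 at 54.7 and the other libraries between -21.7 and -16.2. With 2 libraries against 2, no permutation of the labels can give a p below 0.333.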

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

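The values as deposited, the tests on recovered reads and the removal of the length and GC trend were chosen after the data were seen, and the other alternatives before. Of the 18 alternatives to the gene test, the replicate block called 1 gene as higher, Lars2 (limma, adjusted p 0.0459, against at most 0.960 in the others), and the others called 0. Whether the replicate numbers pair the libraries is not given in the sources used here. The differences between replicates 1 and 2 in young and in aged had a correlation across genes of -0.000384. This cannot exclude a pairing in part of the genes. Relative to all genes tested, the ribosomal list was at 0.28 and 0.18 in young and aged replicate 1 and at -0.15 and -0.25 in replicate 2. The fibroblast markers moved in opposite ways, at -0.65 and 0.09 against 0.91 and -0.31. The block changed no call of a list. The number of lists higher in aged was 0, against 1 in the values as deposited (pericyte markers, adjusted p 0.0280, in a range up to 0.806) and 0 to 6 without a single library. The number lower was 2, against 4 with quantile scaling, 0 with an estimated correlation, 0 with fry and 2 to 7 without a single library. In the fits without a library, the lone library of its age is assumed to vary like the other age. The interferon list was lower in all 22 alternatives and past the threshold in 20, and the oxidative phosphorylation list was lower in all 22 and past it in 19. A list not called at first counts as reversed only if an alternative calls it in the other direction, as happened to 3 lists without a young library. Over the libraries left out, the median of the inflammatory list ranged from -0.620 to 0.0352, that of alternative activation from -0.339 to 0.0906 and that of fibroblast markers from -1.38 to 0.576, and the cause was not tested. In all, 18 of the 32 lists had a median below 0 without one library and above 0 without another. Among those not called in both directions, the median ranged from -0.589 to 0.176 for endothelial markers, from -0.171 to 0.133 for classical monocytes and from -0.0439 to 0.410 for Schwann cells, and that of the ribosomal list, without a change of sign, from -0.373 to -0.0212. The excess of the mean r within an age over that between ages ranged from -0.0218 to 0.0397 without a single library, where it rests on 1 pair within an age. Of 11615 genes tested with both scalings, 2187 (18.8%) had a difference of the other sign in the values as deposited. Depth limits the low genes, with 1 read in a gene of 2 kb worth 0.0435 to 0.0580 FPKM.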

Other observations

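The tests of the read totals, of single libraries and of the number of genes in other splits were chosen after the results were seen. Among 132 gene families formed by symbol, limma's camera called 5, and with an estimated correlation the adjusted p was 0.982 for each of them. None of the 132 families had a lower adjusted p in that setting, so it does not tell these 5 from the others. Of 13 Ccl chemokine genes, which attract leukocytes, 12 had lower mean log2 values in aged macrophages (median -0.58, adjusted p 0.0121), with Ccl3 at 99.0 ± 41.5 and 51.8 ± 8.39 FPKM and Ccl4 at 184 ± 74.6 and 102 ± 22.7 FPKM. Of 11 Ly genes, a symbol shared by lymphocyte antigens, 10 were lower (median -0.70, adjusted p 0.0121), among them Ly6e (337 ± 30.0 and 199 ± 1.83 FPKM), Ly6a (101 ± 33.4 and 49.0 ± 4.81 FPKM) and Ly86 (364 ± 50.8 and 225 ± 45.7 FPKM). The Cox (median -0.46) and Cd genes (median -0.31) were lower with an adjusted p of 0.0131 each. The Ccl call ended in the values as deposited (adjusted p 0.0623), where the median was larger, at -0.93 (quartiles -0.98 and -0.44, against -0.81 and -0.17). Each of the 4 calls ended without at least 1 library, with highest adjusted p of 0.978 for Ccl, 0.152 for Ly, 0.666 for Cox and 0.333 for Cd. With the trend on length and GC content removed, the adjusted p was 0.139, 0.0366, 0.124 and 0.139 in the same order. The medians then were -0.46 for Ccl (quartiles -0.66 and -0.00622), -0.56 for Ly (-0.67 and -0.28), -0.42 for Cox (-0.64 and -0.10) and -0.25 for Cd (-0.49 and -0.03), against quartiles of -0.75 and -0.27 for Ly, -0.74 and -0.19 for Cox and -0.56 and 0.01 for Cd before. The 3 calls thus ended with medians that kept most of their size.

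Of 1108 olfactory receptor genes, which macrophages are not known for, 13 passed the filter of a mean FPKM of at least 1, and 8 of these had over 80% of their summed FPKM in 1 library, an aged library in all 8. The median of 1.19 over the 13 genes (limma's camera, adjusted p 1.05e-04) thus rests on genes that mostly entered through 1 aged library where they were high, and it does not describe the family. Of all 1108 genes, 45.8% and 38.3% had reads in the young and 27.3% and 35.6% in the aged libraries, while 6 and 17 reached 1 FPKM in the young and 21 and 42 in the aged libraries. A value of at least 5 FPKM in 1 library with less than 1 FPKM in the other 3 occurred in 4 and 19 genes in the young and in 28 and 42 genes in the aged libraries. Cd3g was 97.8 FPKM in aged replicate 2 while Cd3d and Cd3e were at most 0.582 FPKM.

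The young libraries stood apart from each other in inflammatory and fibroblast genes. Relative to all genes tested, the inflammatory list was at 0.50 in young replicate 1 and -0.30 in young replicate 2, with -0.05 and -0.10 in the aged libraries, and the fibroblast markers were at -0.65 and 0.91 in the young and 0.09 and -0.31 in the aged libraries.

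The lower interferon response in aged macrophages was weighed against 2 technical explanations, and with the trend on gene length and GC content removed, the adjusted camera p was 4.55e-13 and the median -0.60, which argues against that trend as the whole cause. A single library as the whole cause is argued against by the highest adjusted p of 5.26e-06 without any 1 library, in a range of 1.56e-16 to 0.806 over all alternatives. Correlation between these genes, which answer to the same signal, stays open. With an estimated correlation the adjusted camera p was 0.806. With so few libraries that setting called none of the 32 lists and gave none a lower adjusted p, so it cannot decide. The read totals of the deposited table had been undone before the list was tested, so its adjusted p of 5.58e-13 is no test of them. A difference due to age also stays open, with the list's difference of -0.54 between the ages set against gaps of 0.01 and 0.10 within them, from 2 pools per age.

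The lower oxidative phosphorylation genes kept an adjusted camera p of 0.0301 with the trend on length and GC content removed, with the median moved from -0.32 to -0.25, which argues against that trend as the whole cause. Correlation between these genes stays open, and the adjusted p of fry was 0.322. The adjusted camera p of 0.806 with an estimated correlation cannot decide it, since no list had a lower one in that setting. A candidate explanation that stays open is young replicate 1 alone. Without it the adjusted p was 0.181, in a range of 2.40e-06 to 0.806 over all alternatives, and the median stayed below 0 at -0.23 (quartiles -0.56 and -0.07, from -0.65 and -0.14) but close to the -0.18 of all genes, with which camera compares the list. The split by replicate number, young replicate 2 and aged replicate 2 against the other libraries, also called the list (limma's camera, adjusted p 0.00127), and it called the ribosomal list too. Relative to all genes tested, both lists were highest in young replicate 1 (0.31 and 0.28) and lowest in aged replicate 2 (-0.22 and -0.25). A cause common to both lists was not tested. A difference due to age stays open and was not tested apart from these explanations.

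In the values as deposited most genes seemed lower in aged cells, with a median log2 difference of -0.31 and with 946 lower and 66 higher genes at an unadjusted p below 0.05. The read totals used in turn are a candidate explanation: the reads recovered from each column made up the same share of the total at that column's place, within 0.194 percentage points, and the median moved to -0.09 once the totals were undone. The remaining -0.09 was 0.01 with the median ratio, and whether it reflects scaling or age stays open.

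The 4 libraries allow 3 splits of 2 against 2, too few for a share of splits below 0.05. The real split called 2 lists and the others 12 and 3, so that both other splits called more lists than the real one. The interferon list was called by the real split only. In the other splits its median was 0.16 and -0.02 (limma's camera, adjusted p 0.396 and 0.447). The split with 12 was that by replicate number, with young replicate 2 and aged replicate 2 against the others, and its cause was not tested. The real split gave 773 genes at an unadjusted p below 0.05 and the others 391 and 427, so that neither other split gave as many as the real one.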
